A study of Homo sapiens with 6 samples.

How the data were processed

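The series measured gene expression by mRNA sequencing in WI-38 human embryonic lung fibroblasts. Cells were untreated or exposed to 100 or 200 ug/ml diesel exhaust particles for 24 h, with 2 libraries per group and 6 libraries in all. Groups and replicate numbers were taken from the labels.

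The values used were read counts per gene as deposited by the authors, whole numbers that were not normalised. Reads came from stranded TruSeq mRNA libraries, per the labels' protocols. STAR 2.5, HTSeq 0.9.1 and the build hg38 are named, per the submitters' processing notes. The strand setting of the counting, the annotation release and any read filters were not given in the sources used here. Genes that overlap another gene, on either strand, and genes with close paralogs can therefore share or lose reads, and their values are uncertain. The table held 19391 genes, and 0 sample columns were left unused. All 19391 matched a protein-coding gene of GENCODE release 29 (19951 protein-coding genes), which gave names and coordinates on hg38. Of the 19391 genes, 2431 had no count in any library. Mitochondrially encoded genes were not analysed here.

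Total counts ranged from 8969844 to 13663664 per library. A count of 3, used as the floor for a gene without reads, stood for 0.220 CPM in the deepest library and 0.335 CPM in the shallowest. Reads carry no molecular identifiers, so floors and intervals cover counting error only. These floors are over the library totals. Levels are given in CPM over the TMM-scaled library sizes of the tested genes, as the mean and SD of 2 libraries. Fold changes come from the model and are relative to the same sizes.

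Tests used the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with limma 3.58.1. Genes were kept by the edgeR filter for low counts, with a minimum count of 10 and a minimum total of 15, which left 12770. TMM factors were 1.042 and 0.997 in the controls, 1.075 and 1.070 at 100 ug/ml, and 0.907 and 0.923 at 200 ug/ml. All 6 libraries entered a single fit with the group as the factor and robust empirical Bayes moderation. The residual degrees of freedom were 3, the median prior degrees of freedom 13.1, and the common biological coefficient of variation 14.5%. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes passed at an adjusted p under 0.05. The standard error of a log2 fold change was its size divided by the square root of F. An exact test of 2 against 2 libraries cannot go below a two-sided p of 0.333, so single genes were tested only in the model.

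The groups and comparisons, the model, the alternatives, the gene lists, the marker sets and the rule for named genes were chosen before the data were examined, except where stated. There were 23 lists, of which 22 were tested: targets of the aryl hydrocarbon receptor, NRF2, p53 and ATF4, metallothioneins, heat shock and unfolded protein response, inflammatory, interferon-stimulated and immediate early genes, mitotic and DNA replication genes, matrix genes, matrix proteases, myofibroblast genes, sterol and fatty acid synthesis, lysosome and autophagy, hypoxia and glycolysis, the respiratory chain, apoptosis and iron handling. The list of mitochondrially encoded genes was not analysed here. In 5 marker sets, for fibroblasts and for epithelial, endothelial, leukocyte and mesothelial cells, members were only counted. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. With a correlation estimated for each list, none of the list calls held, and that adjusted p stands beside each. Members were also counted after adjustment over the list alone.

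Named genes were the 10 with the largest rise and the 10 with the largest fall for each dose against control, and 5 and 5 between the doses. They had to pass the test, have a mean log2 CPM of at least 3 and have libraries that did not overlap between groups. Up to 4 members of each list with the smallest adjusted p were named as well, as were genes fixed in advance. List members outside the table were not analysed here, and some genes that the rule would name are not reported here.

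For the genes shared by the doses, 20 sets of unchanged groups were simulated against the same controls. For genes with 1 to 3 counts in a group, the ratio over the TMM-scaled sizes is given with its 95% counting interval. Alternatives were RLE factors, library totals without factors, no count filter, a stricter filter of at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma voom, a fit without robust moderation, fits of only the groups compared, the replicate number as a block, each library left out in turn, and a minimum log2 change of 1. For the lists, an estimated correlation and fry were tried. Removal of a GC trend, by a spline with 5 degrees of freedom per library, was added after the data were seen. Tables were handled with python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.

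The edgeR step was tested on counts simulated for the 12770 genes, with 200 changed per comparison, 100 at each size. For 100 ug/ml against control, 65.0% were recovered at a log2 change of 1 and 93.0% at 2, with 16 false calls (9.20% of calls). For 200 ug/ml against control these were 64.0%, 95.0% and 11 (6.25%). Between the doses 90.0% were recovered at 2 and all 100 at 4, with 16 false calls (7.48%). In the list step, a list of 25 genes shifted by 0.7 had an adjusted p of 2.83e-17 with the preset correlation and 0.0472 with an estimated one. Of 20 random lists 0 were called with either. Genes were simulated independently, so this step does not show how often lists of co-regulated genes are called falsely. The estimated correlation raised the adjusted p of the shifted list although its genes were simulated without correlation.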

Results

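Gene expression was measured by mRNA sequencing in WI-38 cells, a fibroblast line established from human embryonic lung. The cells were left untreated or exposed for 24 h to diesel exhaust particles (DEP) at 100 or 200 ug/ml. DEP are soot particles emitted by diesel engines, which carry adsorbed polycyclic aromatic hydrocarbons and metals. Each of the 3 groups held 2 libraries. Total counts over protein-coding genes were 13663664 and 12110574 in the controls, 12142537 and 10672480 at 100 ug/ml, and 9228730 and 8969844 at 200 ug/ml. Between 14405 and 15502 genes had a count in a library, and 12770 genes were tested after filtering. On log2 CPM, the count scaled to the library total times its TMM factor, the first principal component held 64.5% of the variance and separated the 200 ug/ml libraries from the other 4, and the second held 16.1%. Replicate libraries differed by more than sampling noise in each group, with a chi-square per gene of 33.7 between the controls, 6.81 at 100 ug/ml and 5.86 at 200 ug/ml. By this measure control replicate 1 lay further from control replicate 2 than from the 100 ug/ml libraries (28.7 and 26.3). On log2 CPM the order was the reverse by a small margin. Control replicate 1 had a Pearson correlation of 0.9792 with control replicate 2 and of 0.9781 and 0.9773 with the 100 ug/ml libraries. The replicates correlated at 0.9899 at 100 ug/ml and at 0.9755 at 200 ug/ml, the latter below the controls. On log2 of CPM plus 1, over library totals, control replicate 1 was about as close to control replicate 2 (0.9921) as to the 100 ug/ml libraries (0.9921 and 0.992). The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

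The first comparison asked which genes responded to 100 ug/ml DEP. CYP1B1, a cytochrome P450 induced through the aryl hydrocarbon receptor (chromosome 2, 38066973 to 38109902, hg38), went from 2.998 ± 0.564 CPM (SD, n = 2) in controls to 12.5 ± 0.845 CPM (n = 2), a 4.18-fold rise (log2 fold change 2.06, SE 0.33, edgeR adjusted p = 0.0014). IFIT2, an interferon-induced gene, rose 4.17-fold to 67.8 ± 10.1 CPM (adjusted p = 5.3e-05), and TRIB3, a pseudokinase induced by ATF4, rose 3.73-fold to 125 ± 16.9 CPM (adjusted p = 8.6e-06). HAS2, a hyaluronan synthase (chromosome 8, 121612116 to 121641390), went from 29.5 ± 4.52 CPM to 0.372 ± 0.093 CPM (log2 fold change -6.28, SE 0.37, adjusted p = 1.3e-07). The collagenase MMP1 went from 1095 ± 13.6 CPM to 356 ± 46.3 CPM (-1.62, SE 0.14, adjusted p = 8.8e-06). In all, 556 of 12770 genes passed an adjusted p of 0.05, 187 higher and 369 lower. Both 100 ug/ml libraries lay outside the range of both controls for each of them and for 50.2% of all genes, where chance separates 33.3%. The number of calls depended on single libraries: it was 2935 without control replicate 1, 109 without 100 ug/ml replicate 1 and 122 without 100 ug/ml replicate 2. Each of these fits leaves 1 library in a group, so a lower number does not show that the library left out carried the calls. Scaled by library totals alone, 207 genes were higher and 226 lower.

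Among genes with a mean log2 CPM of at least 3, the other large rises at 100 ug/ml were those of ARC (log2 fold change 3.43, SE 0.53), MX1 (2.11, SE 0.48), IFIT1 (1.97, SE 0.40), NTN4 (1.89, SE 0.21) and APOL6 (1.87, SE 0.27). MT1G (3.16, SE 0.39) and the histone gene H2BC4 (2.29, SE 0.17) also rose, but reads of the metallothionein and histone families can be split between close copies, so these values are uncertain. Besides HAS2, the largest falls among these genes were those of CBLN2 (-3.26, SE 0.28), SLC14A1 (-2.73, SE 0.24), LRRN3 (-2.69, SE 0.25), FAM180A (-2.56, SE 0.27) and INSC (-2.45, SE 0.26). FABP4 (-2.31, SE 0.29), RGS4 (-2.20, SE 0.31) and SOCS2 (-2.19, SE 0.23) followed, together with KRTAP4-12 (-2.30, SE 0.28), which belongs to a family of similar genes. The adjusted p of ARC was 0.26 without control replicate 1 and 0.37 without control replicate 2, and its log2 fold change was 2.28 without 100 ug/ml replicate 1. That of MX1 was 1.39 and 3.49 without control replicates 1 and 2. The adjusted p of MX1 was 0.18 with DESeq2, 0.414 with no count filter, 0.11 without control replicate 1, 0.052 without 100 ug/ml replicate 1 and 0.215 without 100 ug/ml replicate 2. That of IFIT1 was 0.12 with DESeq2, 0.123 with no count filter, 0.32 and 0.21 without control replicates 1 and 2, and 0.25 without 100 ug/ml replicate 2.

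Of the genes fixed in advance, several did not pass at 100 ug/ml: the quinone reductase NQO1 (log2 fold change 0.39, edgeR adjusted p = 0.12), haem oxygenase HMOX1 (-0.16, adjusted p = 0.69), the stress cytokine GDF15 (-0.01, adjusted p = 0.97), the cell cycle inhibitor CDKN1A (-0.03, adjusted p = 0.94), the cytokines IL6 (0.11, adjusted p = 0.93) and CXCL8 (-0.22, adjusted p = 0.65), and COL1A1 (0.14, adjusted p = 0.64). Without control replicate 1, NQO1 (adjusted p = 0.028) and COL1A1 (adjusted p = 0.0099) passed, and without control replicate 2 NQO1 passed (adjusted p = 0.0068). CYP1A1 was below the count filter, with 8 and 0 counts in the controls, 3 and 2 at 100 ug/ml and 0 and 13 at 200 ug/ml.

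Mitotic genes moved down together at 100 ug/ml. Of 21 tested members 18 fell and none rose (20 lower when adjusted over the list alone), with a median log2 fold change of -1.10. The list passed camera, a test of a list against all other genes (adjusted p = 1.3e-28, or adjusted p = 0.11 with an estimated correlation). CDK1, the kinase that drives mitotic entry, went from 43.1 ± 5.56 to 16.7 ± 2.85 CPM (-1.37, SE 0.20), and PLK1 (-1.33), BIRC5 (-1.23) and CDC20 (-1.18) fell with it. Of 25 DNA replication genes 2 fell, RRM2 (-1.07) and RRM1 (-0.59), both subunits of ribonucleotide reductase, and 10 were lower when adjusted over the list alone (camera adjusted p = 1.9e-05, or adjusted p = 0.11 with an estimated correlation). The number of called mitotic genes was 2 without 100 ug/ml replicate 1 and 9 without replicate 2. The adjusted p of CDK1 was 0.062 and that of PLK1 0.054 without 100 ug/ml replicate 1, that of CDC20 was 0.077 without replicate 2, and that of RRM1 was 0.548 and 0.235 without 100 ug/ml replicates 1 and 2 and 0.080 and 0.079 without 200 ug/ml replicates 1 and 2, 0.090 with library totals and 0.076 with only the libraries of both groups. Without control replicate 1 the called DNA replication genes numbered 7, without control replicate 2 they numbered 4, and without any 1 of the treated libraries 1 was called.

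Some matrix proteases and inhibitors also fell at 100 ug/ml. Of 14 members 5 fell (6 adjusted over the list alone), including the inhibitor TIMP3 (-1.78), MMP1 (-1.62), the plasminogen activator PLAT (-1.20) and the stromelysin MMP3 (-1.05) (camera adjusted p = 2.0e-12, or adjusted p = 0.12 with an estimated correlation). Of 16 heat shock genes 3 fell (3 over the list alone), the small chaperones CRYAB (-1.29) and HSPB1 (-0.73) and the mitochondrial co-chaperonin HSPE1 (-1.05) (camera adjusted p = 0.0051, or adjusted p = 0.22 with an estimated correlation). None of the 19 respiratory chain genes passed alone in edgeR, DESeq2 or limma voom (0 over the list alone, 4 at an unadjusted p under 0.05), and their median of -0.22 gave a camera adjusted p = 0.047 (adjusted p = 0.65 with an estimated correlation). Without control replicate 1 the proteases called numbered 8 and the heat shock genes 5. The heat shock list had an adjusted p of 0.070 without 100 ug/ml replicate 2, where 1 of its genes was called, as without replicate 1. The adjusted p of HSPB1 was 0.551 and 0.0894 without 100 ug/ml replicates 1 and 2, 0.108 without control replicate 2, and 0.0736 and 0.0669 without 200 ug/ml replicates 1 and 2. It was 0.0713 with library totals, 0.074 with only the libraries of both groups and 0.0822 with the GC trend removed. That of HSPE1 was 0.198 and 0.109 without 100 ug/ml replicates 1 and 2. Without control replicate 2 the log2 fold change was -0.42 for HSPB1 and -0.58 for HSPE1. The respiratory chain list had an adjusted p of 0.82 without control replicate 2, 0.073 without 100 ug/ml replicate 1, 0.054 and 0.053 without 200 ug/ml replicates 1 and 2, and 0.078 with library totals.

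Interferon-stimulated genes moved up at 100 ug/ml. Of 23 tested members 13 rose and none fell (17 adjusted over the list alone), with a median of 1.68, among them the RNA sensor IFIH1 (1.95), the transcription factor IRF7 (1.79) and IFIT3 (1.60) (camera adjusted p = 1.9e-20, or adjusted p = 0.16 with an estimated correlation). Of 22 ATF4 stress response genes 12 rose and 1 fell (13 and 1 over the list alone), with DDIT4 (1.51), the amino acid transporter SLC7A5 (1.28) and the serine synthesis enzyme PSAT1 (1.27) beside TRIB3 (camera adjusted p = 3.5e-17, or adjusted p = 0.11 with an estimated correlation). Without 100 ug/ml replicate 1 the called interferon genes numbered 8, and without replicate 2 they numbered 3, with adjusted p = 0.17 for IFIH1 and 0.14 for IRF7.

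Some targets of NRF2 and of the aryl hydrocarbon receptor rose at 100 ug/ml, and most tested members of these lists did not pass. Of 26 NRF2 antioxidant targets 6 rose (10 adjusted over the list alone), among them thioredoxin reductase TXNRD1 (1.26), the cystine transporter SLC7A11 (1.14), SRXN1 (0.77) and AKR1C1 (1.13), whose close paralogs make its count uncertain (camera adjusted p = 1.2e-07, or adjusted p = 0.17 with an estimated correlation). Of 5 tested aryl hydrocarbon receptor targets CYP1B1 and STC2 (0.57) rose, with 4 higher adjusted over the list alone (camera adjusted p = 7.3e-05, or adjusted p = 0.12 with an estimated correlation). STC2 is also a member of the ATF4 list, and NQO1 of the NRF2 list. Of 5 metallothionein and zinc export genes 1 rose, MT1G, also 1 over the list alone (camera adjusted p = 0.0011, or adjusted p = 0.18 with an estimated correlation). The called NRF2 targets numbered 2 without 100 ug/ml replicate 1, 3 without replicate 2 and 10 without control replicate 2. The adjusted p of AKR1C1 was 0.18 and that of SRXN1 0.31 without 100 ug/ml replicate 1, and that of SLC7A11 was 0.072 without replicate 2. STC2 did not pass without any 1 of the treated libraries, with adjusted p = 0.21 and 0.45 for the 100 ug/ml and 0.094 and 0.093 for the 200 ug/ml replicates, nor with only the libraries of both groups (0.098) or with the GC trend removed (0.0786). The aryl hydrocarbon receptor targets called numbered 4 without control replicate 1, and the metallothionein list had an adjusted p of 0.26 without control replicate 1 and 4 called genes without control replicate 2.

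**Figure D1:**
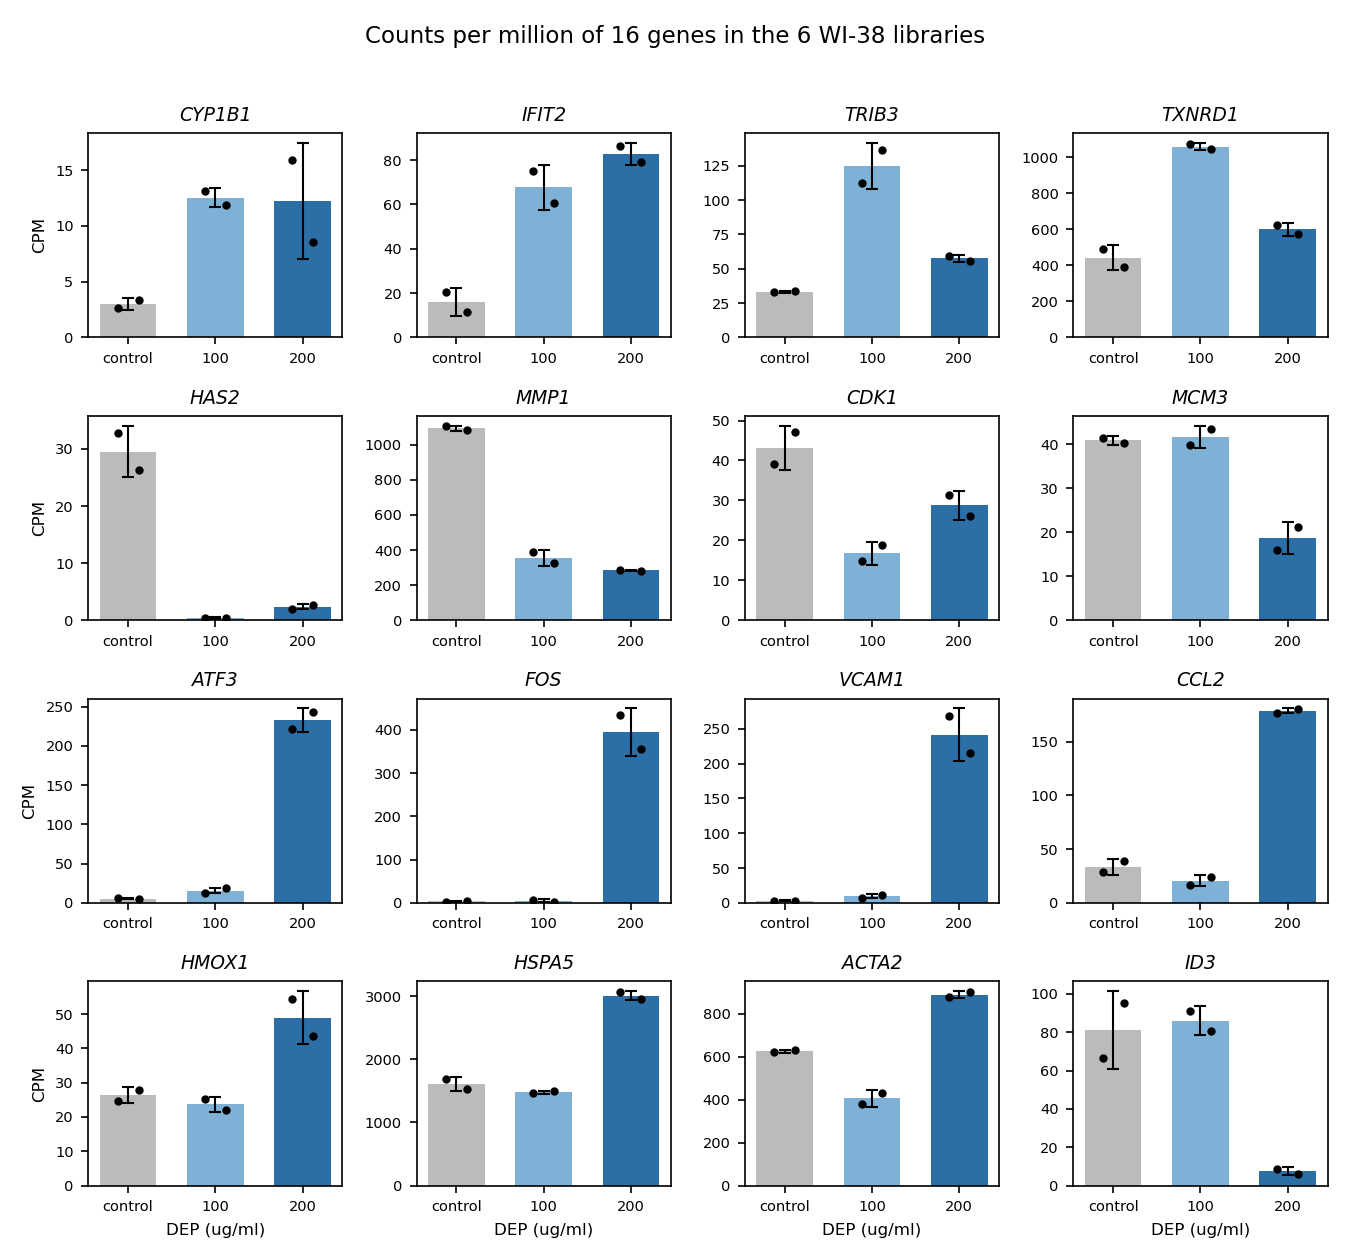
Counts scaled to the TMM-adjusted library size (CPM, y axis, linear, from 0) of 16 genes in untreated WI-38 cells and in cells exposed to 100 or 200 ug/ml diesel exhaust particles (x axis). Bars are group means of 2 libraries, error bars are SD and points are the single libraries. CYP1B1 rose at both doses, HAS2 and MMP1 fell at both, and ATF3, FOS and VCAM1 were higher at 200 than at 100 ug/ml.

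The second comparison asked which genes responded to 200 ug/ml DEP. FOS, an immediate early transcription factor gene, went from 3.28 ± 2.16 CPM (SD, n = 2) to 394 ± 54.8 CPM (n = 2, log2 fold change 6.94, SE 0.38, edgeR adjusted p = 4.1e-09), and ATF3, a member of the ATF4 list (chromosome 1, 212565334 to 212620777, hg38), from 5.56 ± 0.482 to 233 ± 15.0 CPM (5.38, SE 0.21, adjusted p = 1.6e-10). The adhesion molecule VCAM1 rose 78.0-fold, to 242 ± 37.8 CPM (6.28, SE 0.25, adjusted p = 1.6e-10), and the monocyte chemokine CCL2 rose 5.30-fold (2.40, SE 0.20, adjusted p = 3.2e-07). ARC, an immediate early gene best known from neurons (chromosome 8, 142611044 to 142614472), rose from 0.507 ± 0.220 to 549 ± 32.9 CPM (10.08, SE 0.44, adjusted p = 3.3e-10). ID3, an inhibitor of helix-loop-helix transcription factors, went from 81.1 ± 20.3 to 7.39 ± 2.07 CPM (-3.45, SE 0.24, adjusted p = 5.4e-08). In all, 3785 genes passed, 1952 higher and 1833 lower, and the libraries of the groups did not overlap for 99.9% of them and 61.6% of all genes. Without 200 ug/ml replicate 1 the calls numbered 2319. Scaled by library totals alone, which moved the median of all genes from 0.0074 to -0.15, 1382 genes were higher and 2542 lower, so the changes given are relative to the median gene.

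TULP2 had 2 counts over the controls and 759 at 200 ug/ml, a ratio of 600 with a 95% counting interval from 166 to 4966. Intervals and floors given here cover counting error only. Among genes with a mean log2 CPM of at least 3, the other large rises at 200 ug/ml were those of FOSB (log2 fold change 6.43, SE 0.35), MAP3K8 (6.22, SE 0.47), ACKR3 (5.03, SE 0.35) and MYLIP (4.72, SE 0.21). HSPA6 (6.25, SE 0.82) shares sequence with other HSP70 genes and stood at 97.6 and 35.8 CPM in the 200 ug/ml libraries, and its edgeR adjusted p was 0.144 and 0.155 without control replicates 1 and 2 and 0.0764 with no count filter. The largest falls among these genes were those of ESM1 (-4.77, SE 0.36), CBLN2 (-4.66, SE 0.33), KRTAP4-12 (-4.34, SE 0.35), CAVIN4 (-4.09, SE 0.39), HAS2 (-3.65, SE 0.30) and CLDN4 (-3.64, SE 0.33). MARS2 (-3.50, SE 0.41), HMGA2 (-3.43, SE 0.24) and OLFM2 (-3.41, SE 0.32) followed.

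Of the genes fixed in advance, CYP1B1 was 4.09-fold higher at 200 ug/ml (2.03, SE 0.33, edgeR adjusted p = 2.7e-04). HMOX1 (0.89, SE 0.19, adjusted p = 0.0021), NQO1 (0.75, SE 0.13, adjusted p = 6.4e-04), GDF15 (0.92, SE 0.16, adjusted p = 5.3e-04), CDKN1A (0.67, SE 0.13, adjusted p = 8.3e-04) and CXCL8 (1.02, SE 0.23, adjusted p = 0.0034) rose. Without 200 ug/ml replicate 1 CXCL8 had an adjusted p of 0.077. IL6 (-0.34, SE 0.50, adjusted p = 0.65) and COL1A1 (-0.15, SE 0.14, adjusted p = 0.45) did not pass, and COL1A1 passed without control replicate 2 (-0.37, adjusted p = 0.00275).

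Most tested members of the ATF4, NRF2 and iron lists rose at 200 ug/ml. Of 22 ATF4 stress response genes 15 rose and 2 fell (15 and 2 adjusted over the list alone), with a median of 1.05: SESN2 (2.94) and asparagine synthetase ASNS (1.84) rose beside ATF3, and the glutathione-degrading enzyme CHAC1 fell (-2.35) (camera adjusted p = 1.8e-11, or adjusted p = 0.22 with an estimated correlation). Of 26 NRF2 targets 16 rose and 1 fell (16 and 1 over the list alone), including GCLM (1.25), which serves glutathione synthesis, MAFG (0.92), ferritin heavy chain FTH1 (0.80) and AKR1C2 (1.65), a member of a family of close paralogs (camera adjusted p = 2.9e-04, or adjusted p = 0.24 with an estimated correlation). Of 12 iron handling genes 7 rose and none fell (7 over the list alone), with the iron exporter SLC40A1 (2.20), FTH1, ferritin light chain FTL (0.68) and HMOX1 (camera adjusted p = 0.0040, or adjusted p = 0.22 with an estimated correlation). Of 5 aryl hydrocarbon receptor targets 3 rose, STC2 (1.22), CYP1B1 and NQO1, also 3 over the list alone (camera adjusted p = 0.015, or adjusted p = 0.22 with an estimated correlation). STC2 is also a member of the ATF4 list and NQO1 of the NRF2 list. FTH1, FTL and HMOX1 belong to both the NRF2 and the iron lists, so these lists are not independent.

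Of 16 unfolded protein response genes 5 rose and 1 fell at 200 ug/ml (5 and 1 adjusted over the list alone), with HERPUD1 (1.90), the chaperone HSPA5 (0.91), DNAJC3 (0.79) and CRELD2 (0.68) (camera adjusted p = 0.015, or adjusted p = 0.22 with an estimated correlation). Of 19 lysosome and autophagy genes 10 rose and 1 fell (10 and 1 over the list alone), with MAP1LC3B (0.92), NEU1 (0.85) and HEXA (0.69) higher and TFEB, a transcription factor of lysosomal genes, lower (-2.84) (camera adjusted p = 0.015, or adjusted p = 0.22 with an estimated correlation). Without 200 ug/ml replicate 1, 3 unfolded protein response genes and 4 lysosome genes were called higher, the lysosome list had an adjusted p of 0.061 and CRELD2 one of 0.067. Without control replicate 1, 11 unfolded protein response genes were called higher.

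Inflammatory, interferon and immediate early genes also shifted at 200 ug/ml. Of 17 inflammatory genes 9 rose and 3 fell (9 and 3 adjusted over the list alone), with VCAM1, CCL2 and TNFAIP3 (2.27) higher and IL11 lower (-1.62) (camera adjusted p = 1.7e-04, or adjusted p = 0.22 with an estimated correlation). Of 23 interferon-stimulated genes 9 rose (9 over the list alone), among them the chemokine CXCL10 (3.88), IFIT2 (2.35) and IFIT3 (1.19) (camera adjusted p = 1.7e-04, or adjusted p = 0.40 with an estimated correlation). Of 16 immediate early genes 7 rose, among them FOS, FOSB and EGR1 (3.98), and 7 fell (7 and 8 over the list alone). Their median was -0.29 while their mean was 0.96 and the camera direction was up (adjusted p = 0.012, or adjusted p = 0.40 with an estimated correlation). The immediate early list had an adjusted p of 0.235 and 0.083 without control replicates 1 and 2, and 0.496 with no count filter.

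Of 23 p53 targets 9 rose and 2 fell at 200 ug/ml (11 and 2 adjusted over the list alone), with TP53INP1 (1.53) and FDXR (1.08) higher and the kinase PLK3 lower (-1.62) (camera adjusted p = 0.012, or adjusted p = 0.22 with an estimated correlation). Of 17 hypoxia and glycolysis genes 6 rose and 2 fell (7 and 2 over the list alone), with the glycolytic regulator PFKFB3 (2.76), the glucose transporter SLC2A1 (1.05), NDRG1 (0.95) and P4HA1 (0.69) higher (camera adjusted p = 0.044, or adjusted p = 0.22 with an estimated correlation). The hypoxia list had an adjusted p of 0.094 without 200 ug/ml replicate 2 and 0.077 with no count filter. Scaled by library totals alone, its median turned from 0.15 to -0.0027 and its adjusted p was 0.083.

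Most tested mitotic and DNA replication genes fell at 200 ug/ml as well. Of 21 mitotic genes 19 fell and none rose (20 lower adjusted over the list alone), with AURKB (-1.64), BUB1 (-1.45), TPX2 (-1.25) and topoisomerase TOP2A (-1.03) among them (camera adjusted p = 1.5e-07, or adjusted p = 0.22 with an estimated correlation). Of 25 DNA replication genes 18 fell and 1 rose (19 and 1 over the list alone): FEN1 (-1.62), RRM2 (-1.15) and MCM3 (-1.13) fell, and the sliding clamp gene PCNA rose (1.03) (camera adjusted p = 1.9e-06, or adjusted p = 0.22 with an estimated correlation). The mitotic genes called numbered 12 without 200 ug/ml replicate 1 and 10 without replicate 2.

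Matrix genes went both ways at 200 ug/ml. Of 25 collagens and matrix genes 14 rose and 1 fell (14 and 1 adjusted over the list alone), with the collagen COL3A1 (1.28), the proteoglycans LUM (1.12) and DCN (0.89) and thrombospondin THBS1 (1.06) higher (camera adjusted p = 0.0040, or adjusted p = 0.47 with an estimated correlation). Of 14 matrix proteases and inhibitors 5 rose and 6 fell (5 and 6 over the list alone), and MMP1 (-1.95, SE 0.14), MMP3 (-1.55), TIMP3 (-1.43) and the urokinase receptor PLAUR (-1.28) were lower (camera adjusted p = 0.015, or adjusted p = 0.40 with an estimated correlation). Of 10 tested fibroblast markers, COL3A1, LUM and DCN among them, 7 were higher and 1 lower, with a median of 0.83 (7 and 1 adjusted over the list alone). The lower ones numbered 2 without control replicate 2 and 0 without any 1 of the treated libraries. The matrix genes called higher numbered 7 without 200 ug/ml replicate 1 and 9 without replicate 2, and the list had an adjusted p of 0.10 without control replicate 2. The proteases called higher numbered 2 and 3 without 200 ug/ml replicates 1 and 2 and 3 without either 100 ug/ml replicate, and the list had an adjusted p of 0.080 without 200 ug/ml replicate 2.

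**Figure D2:**
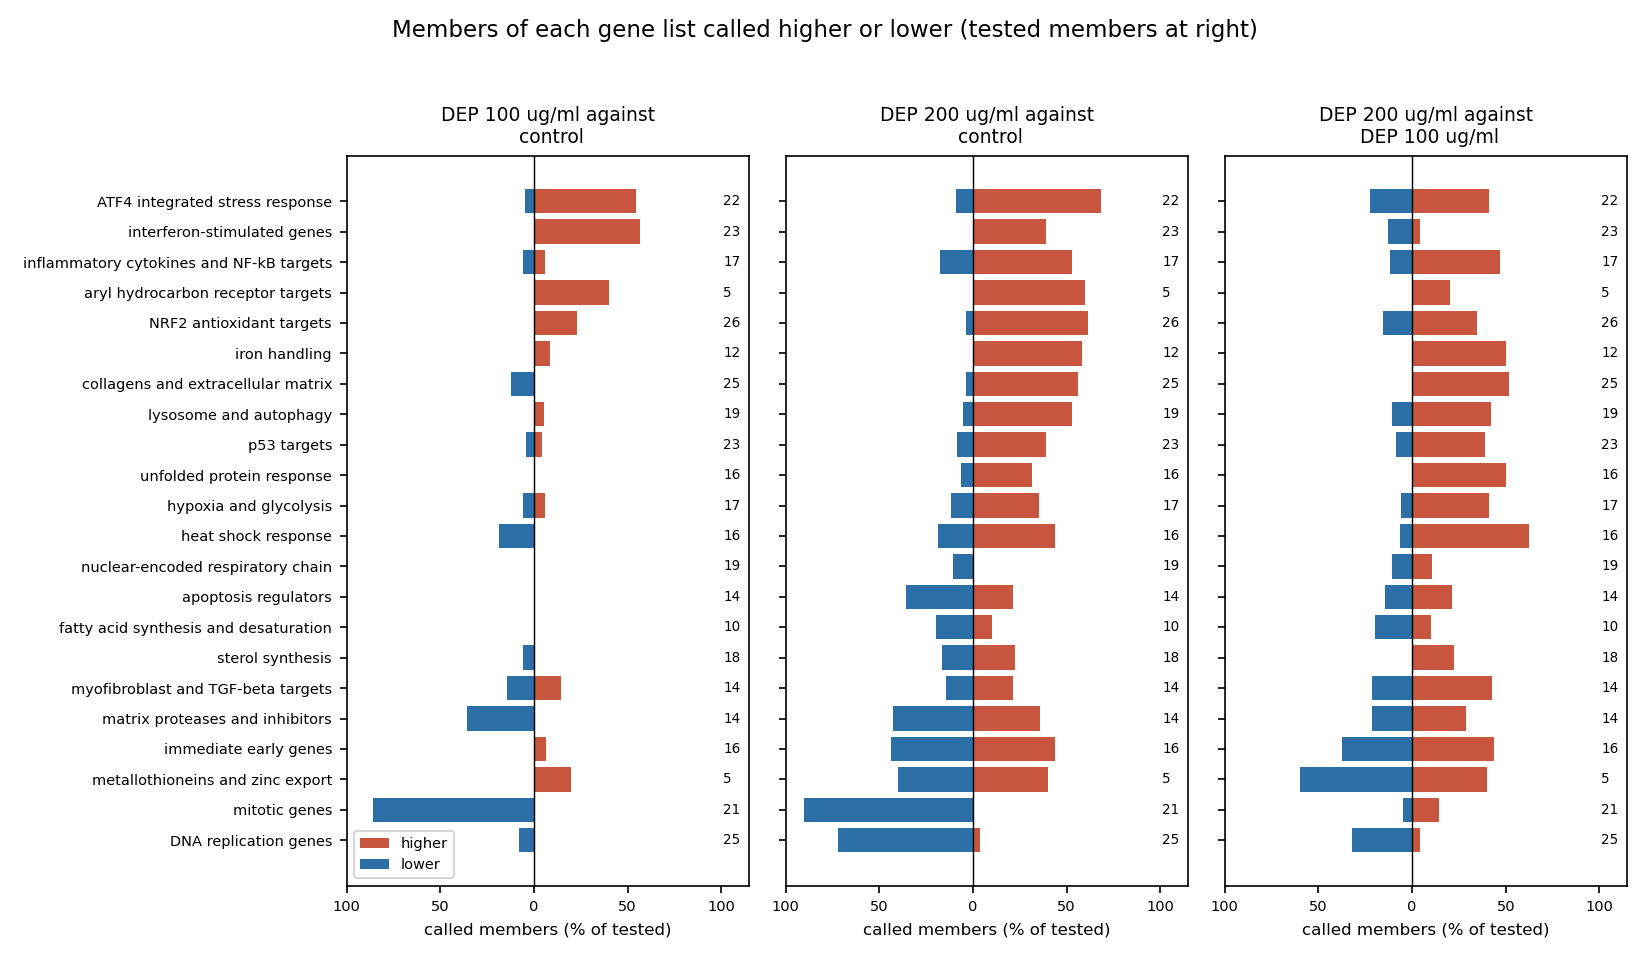
Share of the tested members of each of 22 gene lists called higher (right of 0) or lower (left of 0), in percent (x axis), for the 3 comparisons in separate panels. The number at the right of each bar is how many members were tested. At 200 ug/ml 19 of 21 mitotic genes and 18 of 25 DNA replication genes were lower, and 15 of 22 ATF4 genes were higher.

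The third comparison set the doses against each other, since a gene called at 1 dose and not at the other is not thereby shown to differ. Single immediate early and inflammatory genes were far higher at 200 than at 100 ug/ml, while other members of both lists were lower. The log2 differences were 6.29 for FOS (SE 0.36, edgeR adjusted p = 1.1e-08), 5.56 for FOSB (SE 0.33), 6.65 for ARC (SE 0.34) and 5.29 for the kinase MAP3K8 (SE 0.44). VCAM1 differed by 4.68 (SE 0.22, adjusted p = 2.9e-09) and CCL2 by 3.12 (SE 0.20, adjusted p = 3.7e-08). TULP2 had 2 counts over the 100 ug/ml libraries, which gave a ratio of 558 with a 95% counting interval from 154 to 4617. Among genes with a mean log2 CPM of at least 3, CAVIN4 (-3.81, SE 0.39), ID3 (-3.54, SE 0.24), MARS2 (-3.50, SE 0.41), HPS6 (-3.40, SE 0.24) and TRIM32 (-3.32, SE 0.22) were furthest below. Of 12770 genes 3594 differed, 1972 higher and 1622 lower at 200 ug/ml, and the libraries did not overlap for 70.7% of all genes. The number was 1299 and 1594 without 100 ug/ml replicates 1 and 2, and 1865 without 200 ug/ml replicate 1. Scaled by library totals alone, which moved the median of all genes from 0.030 to -0.20, 1088 genes were higher and 2822 lower.

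Of 16 heat shock genes 10 were higher and 1 lower at 200 than at 100 ug/ml (10 and 1 adjusted over the list alone), with HSPA4L (1.52), CRYAB (1.28) and DNAJA1 (1.24) higher and HSPA8 lower (-0.76) (camera adjusted p = 0.0016, or adjusted p = 0.32 with an estimated correlation). Of 16 unfolded protein response genes 8 were higher (8 over the list alone), with HERPUD1 (1.62), HSPA5 (1.03), DNAJC3 (0.93) and CRELD2 (0.66) (camera adjusted p = 0.0071, or adjusted p = 0.32 with an estimated correlation). The heat shock genes called higher numbered 6 without 100 ug/ml replicate 2 and 5 without 200 ug/ml replicate 1. The unfolded protein response genes numbered 3 and 3 without the 100 ug/ml replicates and 3 and 4 without the 200 ug/ml replicates. For CRELD2 the adjusted p was 0.084, 0.082 and 0.088 without 100 ug/ml replicates 1 and 2 and 200 ug/ml replicate 1, and 0.0501 with library totals.

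Of 17 inflammatory genes 8 were higher and 2 lower at 200 than at 100 ug/ml (11 and 2 adjusted over the list alone), with the NF-kB inhibitor TNFAIP3 (2.89) and TNFAIP6 (2.78) beside VCAM1 and CCL2 (camera adjusted p = 2.9e-05, or adjusted p = 0.32 with an estimated correlation). Of 16 immediate early genes 7 were higher and 6 lower (7 and 6 over the list alone), with JUNB (2.79) and EGR1 (3.01) beside FOS and FOSB. Their median was -0.23 and their mean 0.90, with the camera direction up (adjusted p = 0.0082, or adjusted p = 0.39 with an estimated correlation). Of 22 ATF4 stress response genes 9 were higher and 5 lower (10 and 5 over the list alone): ATF3 (3.89), SESN2 (2.22) and ATF4 itself (1.36) were higher and CHAC1 was lower (-1.53) (camera adjusted p = 0.035, or adjusted p = 0.45 with an estimated correlation). The ATF4 genes called higher numbered 3 and 5 without 100 ug/ml replicates 1 and 2 and 5 without 200 ug/ml replicate 2. The ATF4 list had an adjusted p of 0.13 without 100 ug/ml replicate 1, 0.083 and 0.063 without 200 ug/ml replicates 1 and 2, 0.092 with library totals and 0.15 with no count filter, and the immediate early list had 0.495 with no count filter.

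Of 25 collagens and matrix genes 13 were higher at 200 than at 100 ug/ml and none lower (13 adjusted over the list alone), with COL3A1 (1.27), periostin POSTN (1.15), THBS1 (1.04) and LUM (0.94) (camera adjusted p = 0.0016, or adjusted p = 0.50 with an estimated correlation). Of 25 DNA replication genes 8 were lower and 1 higher (8 and 2 over the list alone), with FEN1 (-1.17), MCM3 (-1.16) and MCM4 (-1.05) lower and PCNA 2.83-fold higher (camera adjusted p = 0.024, or adjusted p = 0.32 with an estimated correlation). Of 17 hypoxia and glycolysis genes 7 were higher and 1 lower (9 and 1 over the list alone), with PFKFB3 (2.19), SLC2A1 (1.12) and P4HA1 (0.86) higher and ANGPTL4 lower (-1.29) (camera adjusted p = 0.030, or adjusted p = 0.32 with an estimated correlation). The matrix genes called higher numbered 8 and 7 without 100 ug/ml replicates 1 and 2 and 8 without 200 ug/ml replicate 1, when the DNA replication genes called lower numbered 3, 4 and 4. The hypoxia genes called higher numbered 3, 3, 4 and 3 without each treated library in turn and 11 without either control. The hypoxia list had an adjusted p of 0.057 without 100 ug/ml replicate 2, 0.077 without 200 ug/ml replicate 2 and 0.082 with library totals.

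Mitotic genes did not pass between the doses (3 higher and 1 lower of 21, camera adjusted p = 0.42), nor did interferon-stimulated genes (1 higher and 3 lower of 23, adjusted p = 0.20), NRF2 targets (9 higher and 4 lower of 26, adjusted p = 0.53) or aryl hydrocarbon receptor targets (1 higher of 5, adjusted p = 0.85). Adjusted over the list alone, the members higher and lower were 1 and 0, 1 and 3, 10 and 4, and 2 and 0. CYP1B1 differed by -0.03 (SE 0.30, edgeR adjusted p = 0.95). Within the NRF2 list GCLM (0.98) and HMOX1 (1.05) were higher at 200 ug/ml, while TXNRD1 (-0.82) and SRXN1 (-0.85) were lower. The mitotic genes called higher numbered 6 without control replicate 1, 0 and 1 without 100 ug/ml replicates 1 and 2, and 0 and 1 without 200 ug/ml replicates 1 and 2. The interferon-stimulated genes called lower numbered 6 without either control and 0 without 100 ug/ml replicate 2 or without 200 ug/ml replicate 2. The NRF2 targets called higher numbered 2 and 2 without the 100 ug/ml replicates and 3 and 5 without the 200 ug/ml replicates.

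The last comparison asked how far the doses changed the same genes. In the same direction at both doses 313 genes were called, 122 higher and 191 lower, including CYP1B1, IFIT2 and MT1G upward and HAS2, CBLN2 and MMP1 downward. Independent lists of these sizes would share 28.6 and 52.97 genes, and unchanged groups simulated 20 times against the same controls shared 0. The simulated groups gave almost no calls, on average 0.3 genes called at 100 and not at 200 ug/ml, so their 0 sets no level for this count. In opposite directions 30 genes were called, 25 of them lower at 100 and higher at 200 ug/ml and 5 the reverse, where independent lists would give 56.4 and 26.8. Across genes, which are not independent replicates, the log2 fold changes of the doses had a Pearson correlation of 0.42 against 0.45 in the simulated unchanged groups, and 61.4% had the same sign against 66.1%. Their covariance was 0.273 against 0.0592, a difference of 0.214. The simulation gave all groups the same spread, while the controls differed by a chi-square per gene of 33.7, against 6.81 and 5.86 at the doses. The simulated covariance may therefore be too low. This rests on the chi-square, since on log2 CPM the controls correlated more closely (0.9792) than the 200 ug/ml replicates (0.9755). With 2 controls neither part of a split would keep 2 libraries, so the controls were not split, and part of the excess may come from the shared controls. Without control replicate 1 the shared genes numbered 1491, and without 100 ug/ml replicates 1 and 2 they numbered 77 and 78.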

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

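The tests of single genes given here belong to the planned comparisons, and the count of genes that moved in opposite directions was chosen only after the results were seen.

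The doses moved some genes in opposite directions. Against control, 30 genes passed at both doses with opposite signs. All of them also differed between the doses in the edgeR test. Opposite calls against the same controls make this all but certain, so that test adds no separate support. Of the 30, 25 fell at 100 ug/ml and rose at 200 ug/ml, and 5 did the reverse. Independent lists of these sizes would give 56.4 and 26.8, so opposite calls were fewer than that. In the same direction 313 genes were called. ACTA2, which encodes the smooth muscle actin of contractile fibroblasts, stood at 626 ± 6.38 CPM (SD, n = 2) in controls, 406 ± 38.8 CPM at 100 ug/ml and 890 ± 15.7 CPM at 200 ug/ml. Its log2 fold changes were -0.63 (SE 0.14, adjusted p = 0.014) and 0.51 (SE 0.14, adjusted p = 0.0098), and the doses differed by 1.13 (SE 0.14, adjusted p = 2.2e-05). LRRN3, a leucine-rich repeat membrane protein, went from 38.5 ± 13.6 to 5.98 ± 1.08 and 76.4 ± 9.20 CPM (-2.69, adjusted p = 1.7e-05, and 0.98, adjusted p = 0.0031). Tissue factor F3, the starter of blood coagulation, chosen after its values were seen, stood at 264 ± 7.13, 101 ± 2.44 and 811 ± 41.2 CPM (-1.39, adjusted p = 2.9e-05, and 1.62, adjusted p = 5.2e-07). ANGPTL4, an inhibitor of lipoprotein lipase, went the other way (0.65, adjusted p = 0.032, and -0.63, adjusted p = 0.0084). The smooth muscle gene CNN1 is not among the 30. It fell to 45.2 ± 1.31 CPM at 100 ug/ml from 114 ± 11.8 CPM in controls. At 200 ug/ml it stood at 101 ± 9.37 CPM, not above control.

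Fits without a library leave 1 library in a group, so a lower count does not show that the library left out carried the result. At 100 ug/ml the log2 fold change of ACTA2 ran from -0.7269 to -0.5315 without each library in turn. The count of opposite genes changed in such fits. It was 102 and 60 without control replicates 1 and 2, 8 and 13 without 100 ug/ml replicates 1 and 2, 15 and 26 without 200 ug/ml replicates 1 and 2, and 54 with no count filter. The edgeR adjusted p of ACTA2 at 100 ug/ml was 0.395 and 0.121 without 100 ug/ml replicates 1 and 2, and at 200 ug/ml it was 0.0829 and 0.0954 without 200 ug/ml replicates 1 and 2 and 0.0548 with library totals. That of ANGPTL4 at 100 ug/ml was 0.588 and 0.0688 without the 100 ug/ml replicates, 0.0644 and 0.0627 without the 200 ug/ml replicates and 0.0682 with only the libraries of both groups. At 200 ug/ml it was 0.134 without 200 ug/ml replicate 1. LRRN3 stood at 0.63 at 200 ug/ml without control replicate 2. No explanation was tested.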

How the results depend on the processing

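Removal of the GC trend was chosen after the data were seen. The counts of genes called, 556 at 100 ug/ml, 3785 at 200 ug/ml, 3594 between the doses and 313 shared, stayed within 1.5 times under RLE factors, library totals, the stricter filter, DESeq2, limma voom, the fit without robust moderation, fits of only the groups compared and the GC trend removed. With no count filter 1047 genes were called at 100 ug/ml and 544 were shared; more genes were tested, and beyond that the cause was not tested. A minimum log2 change of 1 left 266, 1872 and 1623 genes by its construction. Without each library in turn the counts ran from 109 to 2935 at 100 ug/ml, from 2319 to 4527 at 200 ug/ml, from 1299 to 5247 between the doses and from 77 to 1491 for shared genes. Such fits leave 1 library in a group, which is assumed to vary like the other groups, and control replicate 1 moved the counts most at 100 ug/ml. With an estimated correlation camera called 0 lists at 100 ug/ml, 0 at 200 ug/ml and 0 between the doses (6, 3 and 1 at an unadjusted p under 0.05). Fry, which does not compare a list with other genes, called 7, 15 and 12. Of the 10, 15 and 8 lists called by camera with the preset correlation, fry kept 6, 13 and 7. Interferon-stimulated genes did not pass fry at 100 (adjusted p = 0.077) or 200 ug/ml (0.097). Matrix genes did not pass it at 200 ug/ml (0.066) or between the doses (0.068). At 200 ug/ml fry also called heat shock (0.045) and myofibroblast genes (0.012), which camera had not called. Of 3479 values of named genes under an alternative, 3366 kept their direction and side of the threshold, 95 no longer passed, 4 newly passed and 14 changed sign, all of the last from genes that did not pass.

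At 100 ug/ml the log2 fold change of CDKN1A was 0.0464 with library totals and ran from -0.0566 to 0.0037 without each library, that of COL1A1 ran from -0.0512 to 0.3411, that of IL6 from -0.3085 to 0.4362 (-0.1577 without control replicate 1), and that of GDF15 from -0.1596 to 0.1382 (0.0955 without 100 ug/ml replicate 1), with 0.0611 for library totals and 0.0374 with the GC trend removed. At 200 ug/ml COL1A1 ran from -0.3731 to 0.0516 and IL6 from -1.1835 to 0.1926. Between the doses CYP1B1 ran from -0.5436 to 0.3454 and was 0.0103 with the GC trend removed. The cause was not tested.

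With the replicate number as a replicate block 677, 3888 and 3750 genes were called, 370 were shared, and 10, 16 and 8 lists passed. The correlations of same-numbered libraries were 0.142, -0.081 and -0.0136, so the numbers were not read as pairs. Among named genes the block ended the calls of MX1 (adjusted p = 0.116) and IFIT1 (adjusted p = 0.0918) at 100 ug/ml and of IFIT1 (adjusted p = 0.114) and CSF1R (adjusted p = 0.0534) between the doses, and it changed no other named call. The IFIT1 call between the doses also ended with DESeq2 (adjusted p = 0.151), no count filter (0.12) and only the libraries of both groups (0.129). Without each library in turn its log2 difference ran from -2.063 to -0.8164. At totals near 8969844 counts, genes near the floor of 0.335 CPM could not be compared between doses.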

Other observations

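The gene lists and marker sets were planned, as were the tests of depth, of GC content, of length and of the median position of control replicate 1. The tests by shares of genes with a count, the tests with a 100 ug/ml library left out, the test of an exchange of control replicate 1, and the use of the median of matched genes in place of their mean, were chosen only after the results were seen.

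Genes of the contractile and matricellular program split at both doses. Of 14 tested myofibroblast and TGF-beta targets, CNN1 (log2 fold change -1.34) and ACTA2 (-0.63) fell at 100 ug/ml while CCN1 (1.12) and CCN2, which went from 1275 to 2548 CPM, rose (2 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.622). At 200 ug/ml 3 rose and 2 fell (4 and 2 over the list alone), led by CCN2 (1.59), with a median of -0.126, a mean of 0.0673 and adjusted p = 0.603. Between the doses 6 were higher and 3 lower at 200 ug/ml, with CNN1 (1.16) and IGFBP3 (1.09) higher and CCN1 lower (-1.45) (6 and 3 over the list alone, adjusted p = 0.338). Of 25 matrix genes 3 fell at 100 ug/ml, elastin ELN (-2.08) among them (2 higher and 5 lower over the list alone), with a median of 0.030, a mean of -0.118 and adjusted p = 0.693. The myofibroblast genes called lower at 100 ug/ml numbered 6 without control replicate 1 and 1 without either 100 ug/ml replicate, where the adjusted p of ACTA2 was 0.395 and 0.121. At 200 ug/ml 5 were called higher without control replicate 2 and 0 lower without any 1 of the treated libraries, and between the doses the lower ones numbered 5 and 1 in these fits. The matrix genes called at 100 ug/ml numbered 8 higher without control replicate 1, 5 lower without control replicate 2, and 0 and 1 lower without 100 ug/ml replicates 1 and 2, and the adjusted p of ELN was 0.0777 without 100 ug/ml replicate 1.

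Apoptosis, lipid and metal genes also split at 200 ug/ml. Of 14 apoptosis regulators 3 rose, among them the pro-apoptotic BCL2L11 (3.54) and BBC3 (1.82), and 5 fell, among them the survival gene BCL2L1 (-0.72) (3 and 5 adjusted over the list alone, camera adjusted p = 0.929, median -0.00957, mean 0.172). At 100 ug/ml 0 were called by edgeR, DESeq2 or limma voom, with 1 at an unadjusted p under 0.05 (adjusted p = 0.714). Of 18 sterol synthesis genes 4 rose and 3 fell at 200 ug/ml, among the latter the regulator INSIG1 (-1.18) and MSMO1 (-0.77) (4 and 5 over the list alone, adjusted p = 0.603). At 100 ug/ml INSIG1 fell (-0.88), with 3 lower over the list alone and adjusted p = 0.065. Of 10 fatty acid synthesis genes 1 rose and 2 fell at 200 ug/ml, with the desaturase SCD at -1.21 (1 and 2 over the list alone, adjusted p = 0.603), and at 100 ug/ml edgeR, DESeq2 and limma voom called 0, with 1 at an unadjusted p under 0.05 (adjusted p = 0.693). Of 16 heat shock genes 7 rose and 3 fell at 200 ug/ml, with HSPA4L (1.81) and DNAJA1 (1.21) higher and HSPA8 lower (-1.06) (7 and 3 over the list alone, adjusted p = 0.133). Of 5 metallothionein and zinc export genes MT1G (4.12) and the zinc exporter SLC30A1 (1.18) rose and MT2A (-1.14) and MT1E (-1.34) fell (2 and 2 over the list alone, median -0.43, mean 0.477, adjusted p = 0.766), with reads of this family uncertain between close copies.

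Several of these counts changed in fits without a library. Such fits leave 1 library in a group, so a lower count does not show that the library left out carried the calls. The apoptosis genes called lower at 200 ug/ml numbered 3 without 100 ug/ml replicate 1 and 2 and 1 without 200 ug/ml replicates 1 and 2, and at 100 ug/ml 1 was called lower without either control. The sterol genes called higher at 200 ug/ml numbered 2 without control replicate 2, 1 without either 100 ug/ml replicate, and 1 and 0 without 200 ug/ml replicates 1 and 2, and those lower numbered 6 without control replicate 1. MSMO1 had an adjusted p of 0.0717 without 200 ug/ml replicate 2. For INSIG1 the adjusted p at 100 ug/ml was 0.169 and 0.264 without 100 ug/ml replicates 1 and 2, and 3 and 2 sterol genes were called lower without control replicates 1 and 2. The fatty acid genes called higher at 200 ug/ml numbered 0 without control replicate 2 or any 1 of the treated libraries, and those lower numbered 1 without control replicate 1, either 100 ug/ml replicate or 200 ug/ml replicate 1. The heat shock genes called lower numbered 5 without control replicate 1 and 1 without either 100 ug/ml replicate or 200 ug/ml replicate 1.

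The other lists did not pass camera. At 100 ug/ml the adjusted p was 0.693 for the unfolded protein response (edgeR 0 called, DESeq2 1, limma voom 0, 3 at an unadjusted p under 0.05), 0.693 for inflammatory genes, 0.418 for p53 targets, 0.162 for lysosome and autophagy, 0.724 for hypoxia and glycolysis, 0.997 for immediate early genes and 0.065 for iron handling. At 200 ug/ml it was 0.766 for the respiratory chain. Between the doses it was 0.0575 for p53 targets, 0.0773 for iron handling, 0.167 for lysosome and autophagy, matrix proteases and metallothioneins, 0.398 for the respiratory chain and fatty acid synthesis, 0.661 for sterol synthesis and 0.726 for apoptosis.

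Markers of other cell types were mostly below the count filter. Of 10 epithelial markers 3 were tested, and the keratins KRT18 (-0.77 at 100 ug/ml and -0.75 at 200 ug/ml) and KRT19 (-2.34 and -1.61) were lower at both doses (3 lower at each over the list alone). Of 7 endothelial markers 3 were tested, and PECAM1 (5.64, from 4 counts over the controls to 136) and TEK (1.03) were higher at 200 ug/ml (2 over the list alone). Of 8 leukocyte markers 3 were tested, and CD14 (2.38, from 1.18 ± 0.084 to 6.20 ± 0.303 CPM, n = 2) was higher at 200 ug/ml (1 over the list alone). At 100 ug/ml edgeR called 0 endothelial and 0 leukocyte markers, and at neither dose the 1 mesothelial marker tested of 5, with 0 of them at an unadjusted p under 0.05. Of 10 fibroblast markers 1 was lower at 100 ug/ml (1 higher and 2 lower over the list alone), but 4 were higher and 2 lower without control replicate 1, and 0 were called without either 100 ug/ml replicate or without 200 ug/ml replicate 1. Without control replicate 1 edgeR called 1 endothelial marker higher at 100 ug/ml. With no count filter 2 epithelial markers were higher and 2 lower at 200 ug/ml, and the median of the set turned from -0.75 to 0.67, with the added markers at 11 counts or fewer in each library. The adjusted p of KRT18 at 100 ug/ml was 0.169 and 0.235 without 100 ug/ml replicates 1 and 2, and 0.055 at 200 ug/ml without 200 ug/ml replicate 1. That of KRT19 was 0.0993 without control replicate 2 and 0.105 and 0.298 without 100 ug/ml replicates 1 and 2, and at 200 ug/ml 0.163 without control replicate 2 and 0.16 without 200 ug/ml replicate 2.

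Between the doses the endothelial markers PECAM1 (from 3 counts over the 100 ug/ml libraries to 136, a ratio of 66.7 with a 95% counting interval from 22.3 to 327) and TEK (0.93) and the leukocyte markers CD14 (1.89) and CSF1R (1.69, adjusted p = 0.0444) were higher at 200 ug/ml, 2 of 3 tested in each set (2 and 2 over the list alone). Of 10 fibroblast markers 7 were higher and 0 lower by edgeR, DESeq2 and limma voom (7 higher over the list alone, 7 in either direction at an unadjusted p under 0.05), with a median of 0.838, and 1 was lower without either control. Of the 3 epithelial markers tested edgeR, DESeq2 and limma voom called 0, with 0 at an unadjusted p under 0.05, and with no count filter edgeR called 1 higher. The log2 fold change of PECAM1 in the model, 5.93, was 9.52 without 100 ug/ml replicate 2, and against control it was 9.48 without control replicate 2. TEK stood against control at 1.59 and 0.60 without control replicates 1 and 2. Between the doses the adjusted p of TEK was 0.112 without 100 ug/ml replicate 1 and 0.0802 without 200 ug/ml replicate 1, and that of CD14 was 0.0867 without 100 ug/ml replicate 2. CSF1R did not pass without any 1 of the treated libraries (adjusted p = 0.101 and 0.286 for the 100 ug/ml and 0.0813 and 0.131 for the 200 ug/ml replicates), with library totals (0.0751), with DESeq2 (0.0821) or with the GC trend removed (0.0587). The leukocyte markers called higher numbered 3 without control replicate 1, and 1 endothelial marker was lower without 200 ug/ml replicate 2.

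Genes chosen for having no count in the controls cannot fall, so part of any gain follows from the choice. Genes with counts in the controls and none at 200 ug/ml were not counted. Of 4286 genes with no count in either control, 577 had a count in both 200 ug/ml libraries and 205 in both 100 ug/ml libraries. Depth argued the other way. With every library thinned to 8969844 counts the 200 ug/ml libraries still showed on average 937 more genes with a count than the controls. The largest gap between replicates was 719. The thinned 200 ug/ml replicates 1 and 2 had 14783 and 15502 such genes, and the controls 14206 and 14204. By this count 200 ug/ml replicate 1 lay nearer to the controls than to replicate 2. At 200 ug/ml, unspecific background reads alone were argued against as the source of counts in genes within 10 kb downstream of an expressed gene on the same strand. Of these, 32.6% had a count in both 200 ug/ml libraries. Among isolated genes, with no expressed gene within 50 kb and matched on exonic length, 6.78% did, a ratio of 0.208 (95% bootstrap interval 0.16 to 0.266). Without matching, the share of isolated genes was 1.84% at 100 and 6.21% at 200 ug/ml. For the downstream genes it was 13.6% at 100 ug/ml. The downstream genes were thus ahead at 100 ug/ml as well, so the ratio at 200 ug/ml cannot decide what caused the gain. A rise in background over the isolated or the downstream genes was therefore not excluded. For the downstream genes, reads running in from the expressed upstream gene cannot be told apart from transcription of the genes themselves. Genes facing away from an expressed neighbour showed 23.1% at 200 ug/ml, a difference of 9.55 percentage points from the downstream genes (two-sided Fisher exact p = 0.0938). The tests of both explanations planned first gave a difference of median gains of 0 (permutation p = 1) and a ratio of medians of 0, which by their bounds spoke against both, but the medians lay at the log2 gain of a single read (1.14) or at 0 and were set aside as deciding nothing.

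Of 263 tested genes with a single exon 79 were lower and 38 higher at 200 ug/ml, so 30.0% were lower against 14.0% of 12507 genes with more exons. Their median log2 fold change was -0.18 against 0.01, and in each pair of a 200 ug/ml library and a control their median lay below that of the other genes, by -0.155 to -0.184. Against 10 multi-exon genes matched on GC content the median difference was -0.2748, and against 10 matched on length it was -0.2218. Each had a permutation p of 1e-04, the smallest that the permutations can give. They permute genes, so this p does not measure the spread between libraries. Matching on either property did not shrink the gap. Computed first against the mean of the matched genes, the differences were -0.371 and -0.355. Reads shared between close copies were not tested, and no biological explanation was tested.

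The controls differed from each other by a chi-square per gene of 33.7, against 6.81 and 5.86 between the replicates of the doses. On log2 CPM the controls correlated at 0.9792, between the replicates at 100 ug/ml (0.9899) and at 200 ug/ml (0.9755), so the larger distance of the controls holds for the chi-square and not for this measure. An exchange of control replicate 1 with a 100 ug/ml library was argued against, because that library would lie beside control replicate 2. Both 100 ug/ml libraries lay further from it (correlations 0.9657 and 0.969) than any replicates from each other, with a ratio of distances of at least 1.27. A single 100 ug/ml library labelled as a control was argued against by the share of genes nearer to control replicate 2. Only 2 libraries left out set the spread for this share. Over genes called without control replicate 1 and without 1 of the 100 ug/ml libraries, control replicate 1 lay nearer to control replicate 2 at 36.3% and 37.5%, and the 100 ug/ml library left out at 7.40% and 2.96%. The smallest gap was 28.9 percentage points, against a spread of 4.44 between the libraries left out. The median positions were less clear. Over 2935 genes called with control replicate 1 left out, its median position between control replicate 2 (at 0) and the mean of the 100 ug/ml libraries (at 1) was 0.6517 (95% bootstrap interval over genes 0.6345 to 0.669), under the bound of 0.75 set for the test. The libraries left out lay at 1.046 and 0.8213, where control replicate 1 lay at 0.6436 and 0.6192, and this gap of 0.178 is smaller than their spread of 0.225. Mixed material and a difference in culture state were not tested, and no batch is given in the labels.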
